A study of Rattus norvegicus with 8 samples.

How the data were processed

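Gene expression was measured in the lower lumbar spinal cord of Sprague Dawley rats, an outbred laboratory strain, with CEL-Seq2. CEL-Seq2 reads the 3' end of each polyadenylated transcript and tags each captured molecule with a short random identifier, so that copies made during amplification are counted once. According to the labels, 4 libraries came from animals without an injury and 4 from animals 4 days after a hemisection at thoracic level 9. Each library was 1 column of a single table.

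The deposited values are counts: whole numbers of molecules per gene with no normalization, as the column totals, which differ between libraries, also show. The submitters' processing notes name HISAT2 2.0.4, HTSeq 0.6.0 and the rat genome build Rnor_6.0. The step that collapsed identifiers, the annotation release and any filter on reads are not given in the sources used here. The table held 32883 Ensembl gene identifiers, of which 19915 had no molecule in any library. It contained no row for unassigned reads and no column beyond those of the 8 libraries.

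The table gives identifiers without symbols, and none of the 4159 tested identifiers could be paired with a symbol through the reference table used here, in which the Ensembl field was blank for all 47357 genes. The gene lists for cell types and pathways that had been fixed before the data were examined were therefore not tested, and neither were the cell type marker comparison and the genes chosen by name. Genes are described by number, direction, size and abundance. The 2 identifiers given as higher follow the rule fixed in advance for the largest rises, except that the rule excluded genes without a symbol. The 2 given as lower are those with the smallest p among lower genes and were chosen after their values were seen.

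Genes were kept with edgeR's filterByExpr at its default settings, a minimum count of 10 and a minimum total of 15, which left 4159 genes holding 92.5% to 94.3% of the molecules of each library. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, TMM factors, robust fit), two-sided, with Benjamini-Hochberg adjustment over the 4159 genes and a threshold of 0.05. Standard errors of log2 fold changes were derived from the fitted value and the F statistic. CPM values are counts relative to the library's molecules in the 4159 tested genes, with that total multiplied by the TMM factor. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run as alternatives, with other scalings, filters and thresholds and with each library left out in turn. Correlations across genes used log2 CPM with a prior count of 3. Plots were drawn with matplotlib 3.10.9.

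The titles number the libraries 1 to 4 in both groups without saying what the numbers mean, and the main fit ignored them. A check on the log2 CPM values showed that libraries with the same number deviated from their group means together. The correlations across genes of these deviations were 0.39, 0.36, 0.17 and 0.45 for numbers 1 to 4, and between 0.24 and -0.39 for different numbers. All 8 libraries correlated best with the library of their own number in the other group. For uninjured replicate 3 the margin was small, 0.17 with injured replicate 3 against 0.16 with injured replicate 4. The numbers were therefore treated as pairs, on the data rather than on a stated design, and results with the number as a block are given beside those without it. No 2 columns were identical, and the most similar libraries of 1 group differed by a chi-square of 3.18 per degree of freedom, above counting noise, so that none was treated as the same library deposited again. The labels do not state that each library came from a separate animal, and p-values measure the spread between these libraries.

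The test was checked on simulated data for the comparison of 4 injured with 4 uninjured libraries, with 4159 genes drawn from the measured means, dispersions and library sizes. In each of 5 repeats, 200 genes were changed. Each fold was split evenly between the groups to keep the mean abundance, so that a simulated fall mirrors a rise. The test recovered 96.0% of 4-fold rises, 94.0% of 4-fold falls, 38.0% of 2-fold rises and 33.6% of 2-fold falls, and 8.3% of the called genes had not been changed.

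Depth was low and uneven. Totals ran from 119808 to 405537 molecules, a ratio of 3.38, and 3 molecules corresponded to between 7.20 and 34.8 CPM. Intervals given for shares cover counting error only. The most abundant genes met a limit: the highest count of each library lay between 3989 and 4080 despite the range of totals, and 6 bases allow 4096 different identifiers. The length of the identifiers is not given in the sources used here. The 6 genes that exceeded 3500 molecules in any library are compressed by such a limit, and a correction for repeated identifiers was run as an alternative. The highest count of any gene called as changed was 877, for which the correction adds 12.5%.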

Results

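The series asked how an injury at thoracic level changes gene expression in lower, intact spinal cord. The cord was cut on one side (hemisection) at thoracic level 9, and the lower lumbar cord was sampled 4 days later. Molecule counts were available for 4 injured and 4 uninjured libraries. The labels do not say whether uninjured animals had a sham operation, nor which side of the cord was sampled. Uninjured libraries held 374649, 238236, 119808 and 405537 molecules in replicates 1 to 4, and injured libraries held 358817, 378725, 153060 and 257354. The totals of the groups did not differ by an exact two-sided permutation test (p = 0.943). Between 7733 and 10450 genes had at least 1 molecule. Libraries numbered 3 were the shallowest of each group, and their 10 most abundant genes took 24.6% of the molecules in the uninjured and 18.5% in the injured library, against 8.88% to 13.3% in the other 6. The highest count of each library lay between 3989 and 4080 whatever its total, so that a shallower library gives such genes a larger share.

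At 4 days after injury, 41 of 4159 tested genes were higher in the lower lumbar cord and 0 were lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median fold change of the 41 genes was 3.68, with a range from 2.06 to 10.3. These sizes depend in part on what the test could detect, since it recovered 38.0% of simulated 2-fold rises. A rise of 4-fold or more was fitted for 16 genes, and the other 25 rose between 2-fold and 4-fold. Over all 4159 tested genes, 128 had every injured library above every uninjured library in CPM and 74 had every injured library below, where chance gives about 59 genes in each direction. That chance value takes all 8 libraries as exchangeable and ignores the pairing by number. Symbols could not be assigned to the identifiers, so these genes are not grouped by function here.

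**Figure D1:**
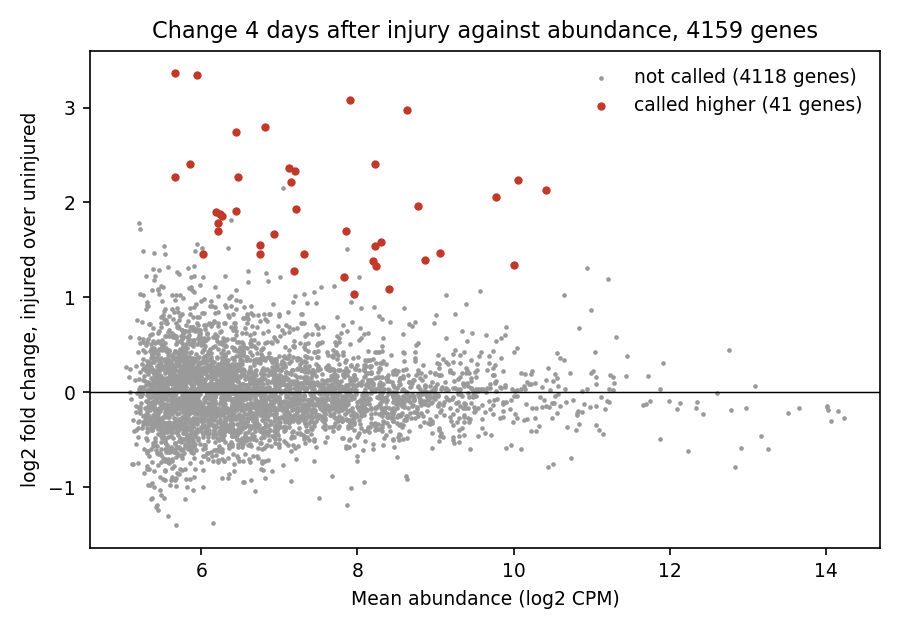
Log2 fold change of injured over uninjured libraries (vertical axis) against mean abundance in log2 CPM (horizontal axis), with 1 point per tested gene. The 41 genes called higher are red and the 4118 others are grey, and no gene was called lower.

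Averaged over all 8 libraries, the 41 genes had 39.1 molecules per library at the median, against 23.9 for all tested genes, with a range from 11.6 to 375. This mean includes the injured libraries, in which the genes were called higher. The rise itself adds to it, so it does not give their abundance without injury. Of the 41 genes, 18 averaged at least 50 molecules per library and 23 averaged between 10 and 50. Together they took 0.451% ± 0.0921 of all molecules in uninjured libraries (SD, n = 4) and 1.59% ± 0.296 in injured libraries (SD, n = 4), a ratio of 3.52. Because the genes were chosen on these libraries, this ratio describes them and is no independent test. The share was 1.59%, 1.78%, 1.17% and 1.81% in injured replicates 1 to 4, and 0.352%, 0.507%, 0.548% and 0.397% in uninjured replicates 1 to 4. The exact 95% binomial interval was 0.507% to 0.592% in uninjured replicate 3 and 1.11% to 1.22% in injured replicate 3, the shallowest library of each group. By replicate number, the ratio of injured to uninjured was 4.52, 3.50, 2.13 and 4.56.

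**Figure D2:**
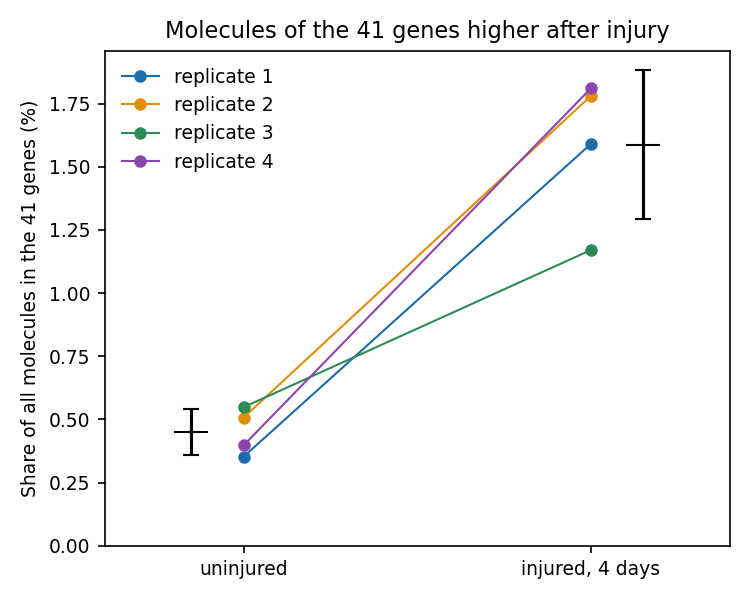
Share of all molecules, in percent, held by the 41 genes in each library, with a line joining libraries of the same replicate number and black bars for the mean ± SD of each group (n = 4). The injured libraries lie between 1.17% and 1.81% and the uninjured between 0.352% and 0.548%.

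The 2 largest fitted rises were close, and both genes were near the detection limit without injury. ENSRNOG00000015131 stood at 6.98 ± 8.59 CPM in uninjured and 75.6 ± 19.7 CPM in injured libraries (SD, n = 4 each). Its log2 fold change was 3.36 with a standard error of 0.55 (edgeR adjusted p = 0.00321), and it was called in all 8 fits that left out 1 library. Its counts were too low to be tested in 3 other settings. These were a filter of at least 20 molecules in at least 4 libraries, thinning to the lowest total, and replicates 3 and 4 alone. It had 4, 4, 0 and 0 molecules in uninjured replicates 1 to 4 against 34, 34, 7 and 15 in the injured ones, and its log2 fold change moved to 2.74 without uninjured replicate 4 and to 4.00 without uninjured replicate 2. ENSRNOG00000024650 stood at 10.8 ± 9.03 CPM in uninjured and 93.2 ± 55.3 CPM in injured libraries (SD, n = 4 each). Its log2 fold change was 3.34 with a standard error of 0.61 (edgeR adjusted p = 0.00927). It had 0, 5, 1 and 4 molecules in uninjured replicates 1 to 4 against 19, 65, 8 and 20 in the injured ones, and its log2 fold change moved to 2.75 without uninjured replicate 1 and to 3.99 without uninjured replicate 2. The call was lost in 4 of 25 alternatives, given with their log2 fold changes: with limma-voom (3.35, adjusted p = 0.0571), without uninjured replicate 4 (3.37, edgeR adjusted p = 0.0659), in replicates 1 and 2 of both groups alone (3.72, edgeR adjusted p = 0.368) and in replicates 3 and 4 alone (2.82, edgeR adjusted p = 0.591). The order of the 2 genes reversed in several fits that left out 1 library.

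No gene was lower at the adjusted threshold. At an unadjusted p under 0.05, edgeR gave 222 higher and 104 lower genes without the replicate block, and 355 higher and 236 lower genes with it, where chance alone gives about 104 in each direction. DESeq2 called 56 higher and 3 lower genes, and limma-voom called 46 higher and 1 lower. The 95% interval of the fold change excluded a fall of 4-fold or more for 4138 genes (99.5%) and a fall of 2-fold or more for 3339 genes (80.3%). A rise of 2-fold or more was excluded for 3290 genes (79.1%). The smallest p among lower genes belonged to ENSRNOG00000024506, with a log2 fold change of -1.11 (standard error 0.27, edgeR adjusted p = 0.0544). It stood at 245 ± 65.4 CPM in uninjured and 113 ± 19.6 CPM in injured libraries (SD, n = 4 each). ENSRNOG00000003386 had a log2 fold change of -1.38 (standard error 0.34, edgeR adjusted p = 0.0593).

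With the replicate number as a block, 94 genes were higher and 16 were lower after injury, including all 41 genes called without it. The blocked fit lowered the common dispersion from 0.0684 to 0.0254. Genes called higher had a median fold change of 2.53, and 85 of the 94 were higher in all 4 pairs. The falls were smaller: they ranged from 1.5-fold to 2.71-fold with a median of 1.90-fold, 3 of them reached 2-fold, and 16 of 16 were lower in all 4 pairs. Since genes called with the pairs in the fit are chosen for agreeing over these pairs, both counts over pairs are no independent test. Both lower identifiers passed in the blocked fit. The log2 fold change was -1.09 for ENSRNOG00000024506 (edgeR adjusted p = 0.0041) and -1.44 for ENSRNOG00000003386 (edgeR adjusted p = 0.0133). Without the block, each passed in only 1 of the 8 fits that left out 1 library.

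**Figure D3:**
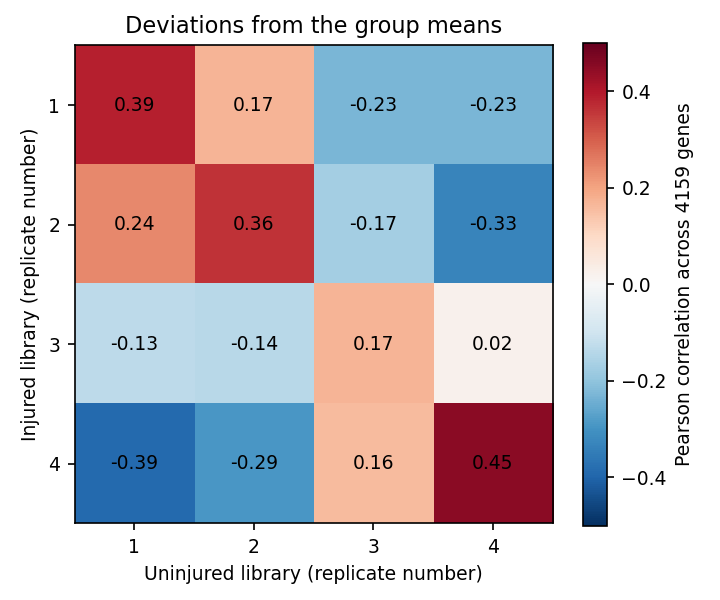
Pearson correlations across 4159 genes between the deviations of each injured library (rows) and each uninjured library (columns) from their group means. Values on the diagonal, for libraries of the same replicate number, run from 0.17 to 0.45, and those off it from -0.39 to 0.24.

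Replicate numbers also divided the libraries more broadly. Numbers 1 and 2 of both groups differed from numbers 3 and 4 in 166 genes by the same test, the highest count among the 35 splits into 4 and 4. That fit counts same-numbered libraries as separate replicates although they deviate together, so its count can be too high. Within numbers 1 and 2 alone, 82 genes were higher and 4 lower after injury, and the 41 genes had a median fold of 3.83. Within numbers 3 and 4 alone, where 2 libraries faced 2 and depth was lower, 3 genes were called and all were higher. The 39 of the 41 genes that could be tested there had a median fold of 3.47. Since the 41 genes were chosen on all 8 libraries, their rise within either set of numbers is no independent test. With this division as a term, 66 genes were higher and 6 lower.

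Single libraries affected the number of calls. Leaving out 1 library at a time gave between 23 and 77 called genes. The count was 23 without uninjured replicate 1 (22 higher, 1 lower), 23 without uninjured replicate 4 (all higher) and 77 without uninjured replicate 3, the shallowest library (74 higher, 3 lower). The other 5 fits called no gene lower. Of the 41 genes, 19 were called in all 8 of these fits.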

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

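All settings that thinned counts, corrected for identifiers, dropped abundant genes, used total counts or a centred median, or used the number groups 1 to 2 and 3 to 4 were chosen after seeing the data, as was leaving out both libraries numbered 3. The main count of 41 called genes stayed within 1.5 times under DESeq2, limma-voom, 4 other scalings, the stricter filter, library size as a covariate, both other thresholds, the non-robust fit, the correction for repeated identifiers and the removal of the 25 most abundant genes. It rose to 98 with no filter on low counts (94 higher, 4 lower) and to 110 with the replicate block (94 higher, 16 lower). It fell to 22 in a median draw with all libraries thinned to 119808 molecules (19 to 25 over 10 draws), where fewer genes could be tested. It was 62 without both libraries numbered 3, and 383 when these were left out and the replicate block was used (272 higher, 111 lower). It was 72 with the 2 number groups as a term, 86 in numbers 1 and 2 alone and 3 in numbers 3 and 4 alone. Leaving out 1 library gave 23 to 77. Thinning equalizes totals and leaves the shares of genes within a library in place. Other causes of these moves were not tested. None of the 41 genes changed direction in any of the 29 alternatives in which it was tested. Of 100 values of the 4 named identifiers under alternatives, 81 kept their side of the threshold, 15 gained significance, 4 lost it and 0 changed sign. In all 27 alternatives that refitted the genes, more genes were higher than lower at an unadjusted p under 0.05. The planned tests of gene lists and cell type markers were not run, since no identifier had a symbol. At these depths and dispersions, 38.0% of simulated 2-fold rises and 33.6% of 2-fold falls were recovered.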

Other observations

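Of the tests below, those of scaling and of a batch were chosen after the result they bear on had been seen, and so were the further settings of the correlation among the 41 genes.

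The 41 genes varied together beyond the difference between the groups. After group and replicate number were removed, their mean pairwise correlation was 0.53. The median of 1000 random lists matched on abundance was -0.01, and the correlation lay at percentile 100 of these lists. With both removed, this value reflects how the injured-minus-uninjured difference varied between replicate numbers, not spread among libraries of 1 group. The injured to uninjured ratio of the share held by the 41 genes was lowest for number 3. It was 2.13 there, against 3.5 to 4.56 for the other numbers. Uneven depth with low counts was argued against: with all libraries thinned to one total and lists matched on both group means, the correlation was 0.41 and the percentile again 100. Among the 18 genes with at least 50 molecules it was 0.50 in uninjured libraries alone and 0.21 in injured libraries alone, with 95th percentiles of random lists at 0.09 and 0.12. Uninjured replicate 3 carries much of it, since with group alone removed it fell from 0.42 to 0.19 without that library, still above the 95th percentile of 0.12. No biological explanation was tested, since the genes have no symbols here.

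The calls lay in one direction, 41 higher and 0 lower. Under 4 other scalings, 41 to 44 genes were called higher and 0 lower, but these moved the median log2 fold of all tested genes by at most 0.01, too little to test scaling as a cause. Less power for falls stays open for falls under 4-fold. For falls of 4-fold or more the 95% intervals argue against it. They excluded such a fall for 4138 of 4159 genes (99.5%), while 16 genes had a fitted rise of 4-fold or more. Among 1073 genes with at least 50 molecules, 29.4% of those at an unadjusted p under 0.05 were lower (25 lower against 60 higher; exact 95% binomial interval 20% to 40.3%), and the upper end misses the bound of 40% set in advance. Among the same genes 18 were called higher and 0 lower. Both this count and the binomial interval treat genes as independent. Genes that vary together are not, so the interval can be too narrow. In simulated data 94.0% of 4-fold falls and 96.0% of 4-fold rises were recovered. Each fold was split evenly between the groups there, so near-equal recovery follows from the settings. It does not decide whether power differs between falls and rises. The blocked fit called 16 genes lower, so that the absence of falls does not hold once replicate number is taken into account. Nor does it hold in every fit without the block. DESeq2 called 3 genes lower, limma-voom 1 and the fit with no filter on low counts 4.

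Of the 35 splits of the 8 libraries into 4 and 4, 2 gave at least 41 called genes, the real one included, so that chance is not excluded over all splits. The other was numbers 1 and 2 against 3 and 4, with 166 genes, a count several times the real one that points to a structure of the samples. That split keeps all 4 pairs together and counts paired libraries as separate replicates, so the 2 counts are not on an equal footing. Of the 8 splits that part all 4 pairs, the real one gave 41 and the highest other 1, which are too few splits for a share under 0.05. The excess of higher over lower genes at an unadjusted p under 0.05 was 118 in the real split and 123 in the highest other, and 2 of 35 splits reached at least 118. The split with 123 set uninjured replicates 1, 2 and 4 with injured replicate 3 against the others, and called 0 genes. It also parts all 4 pairs and is the real split with the libraries numbered 3 exchanged. It keeps most of the injury contrast and is a poor sample of chance. By the counts of splits, chance is still not excluded for that excess in either set.

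The 166 genes that part numbers 1 and 2 from 3 and 4 had a median absolute fold of 2.16, with 96 higher and 70 lower in numbers 3 and 4. Unequal totals were argued against as the whole cause. With all libraries thinned to 119808 molecules, this split still called 73 to 108 genes. The median was 91.5, against a median of 22.5 for injury. The size of that gap is not to be read closely, since this split keeps the pairs together and the injury split parts them. Thinning leaves in place the larger share of molecules that the most abundant genes took in the libraries numbered 3. That share goes with low depth, and these libraries lie on the same side of this split. The thinned counts therefore do not decide whether depth acts through that share. A batch shared across the groups, such as a day of surgery, dissection or library preparation, may account for the 166 genes, but no source used here names one, and it cannot be told apart from differences between the tissue samples.

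With totals thinned to one number of molecules, uninjured replicate 3 stood farthest from the other uninjured libraries. Its distance was 1.21 times that of the next most distant one. Thinning leaves its larger share of molecules in the 10 most abundant genes in place. Since the highest counts met the same limit in every library, that share goes with low depth, and the distance is not free of depth. In the fit without uninjured replicate 3, thinning another uninjured library to its depth gave a median of 66 called genes over 15 draws, with a range of 53 to 75.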
